A study of Homo sapiens with 2 samples.

How the data were processed

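Small RNA and gene expression were measured in U87MG, an established human glioblastoma cell line, without any treatment. The series holds 2 libraries, 1 of small RNA and 1 of mRNA, with no replicate and no control cell. Per the labels, the cells grew in MEM with 10% FBS and 1% antibiotics, and RNA was extracted with Trizol. The RNA integrity number in the labels was 8.7 for the small RNA and 9.3 for the total RNA. Per the labels, the small RNA library was made with a NEBNext small RNA kit and read as single-end reads of 50 bases. For the mRNA library, the labels repeat that same small RNA protocol, whereas the series text speaks of paired-end reads for the transcriptome. How the mRNA was selected is therefore not given in the sources used here.

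The small RNA values are read counts, per the file headers, given by the authors for each mature miRNA and for each entry of a piRNA database, with the sequence of each. They were not normalized. The mRNA values are FPKM (fragments scaled by gene length and by the size of the library), per the file headers, given by the authors for each Ensembl gene. The submitters' processing notes name cutadapt, an adapter trimmer, and the human builds hg19 and GRCh37, with no version or role. The aligner, the read counter, the rule for reads that match several entries, the FPKM program and the annotation are not given in the sources used here. Every listed entry had at least 1 read or an FPKM above 0. An entry that is absent is described as having no row and was given no upper limit. A missing row is not by itself read as a lack of expression, because some genes that all cells use had none. The rule for shared reads matters for families: 24 miRNA names shared 9 mature sequences, and all 9 sequences had unequal counts under their names, so identical miRNAs had not been counted alike. miR-365a-3p had 193 reads and miR-365b-3p, of the same sequence, 1648.

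Gene names were matched by Ensembl identifier, then by symbol, then by older symbol. Of the 21445 gene identifiers, 20595 were found in the gene name table and 850 were not. The order of neighbouring genes came from RefSeq genes on GRCh38, used for names and order only. No coordinates are printed because the files give none and the builds differ.

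Shares of reads are given with exact Clopper-Pearson 95% intervals. Reads without molecular identifiers are not independent molecules, so the intervals cover counting error only. Depth was 11785001 miRNA reads and 27299683 piRNA reads. The depth of the mRNA library is unknown, so FPKM values have no interval. A miRNA or piRNA was counted as detected at 10 reads and a gene at an FPKM of 1. Arm use was computed for hairpins with both arms listed under the same name and at least 100 reads together. For each gene list the median of log2(FPKM + 1), with a pseudocount of 1, was taken over the members with a row and set among 10000 random lists of the same number of genes, drawn from all listed genes. A median above the 97.5 or below the 2.5 percentile was taken to stand apart. This percentile describes 1 library and is no test between conditions. In simulated data built from the 21445 genes, 10% of 40 unshifted lists of 12 genes fell outside these percentiles, against 27.5% of lists shifted by 1 on the log2 scale, 67.5% at 2 and 90% at 3. The relation between miRNAs and the genes listed as their hosts was tested across 50 pairs with Pearson's r and Spearman's rho on log2(value + 1). It used 100000 permutations of the pairing, two-sided, and the strand of the pairs was not checked. A miRNA or host gene without a row entered these pairs as 0, and the relation was repeated without such pairs. It was the only relation tested between the libraries, and its p-values, also those over other sets of pairs, were not adjusted. Genes are not independent replicates, and the hosts DALRD3 and GABRE each stand in more than 1 pair, which the permutation ignores.

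The groups, the 21 gene lists, the 14 miRNA lists, the 50 pairs, the thresholds and most alternative settings were chosen before the data were examined. Named were the 15 miRNAs with the most reads, the 3 highest members of each miRNA list and its members with no row, the 10 piRNAs with the most reads, the 15 genes with the highest FPKM, and from each gene list the 4 highest and the 2 lowest members, with those lacking a row first. A few items that this rule names are not reported here. Names outside this rule were chosen after their values were seen. The alternative settings were other read minimums, FPKM thresholds and pseudocounts, other denominators and random pools, collapsed sequences and other sets of pairs. A planned comparison with annotated tRNA and rRNA needed a genome, which was not used here. In its place, piRNA entries were compared with 21 sequences of tRNA, mitochondrial tRNA, rRNA, Y RNA and 7SL RNA written from general knowledge, in full or in part. An entry matched if it shared 20 bases in a row with one of them. Because the set is partial, a share of matching reads is a lower bound. Further alternatives added after the data were seen are named with the closing results. The length column of the FPKM values has no stated unit and was left out. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.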

Results

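The series set out to find known small RNAs and mRNAs that might take part in the growth of glioblastoma, a malignant brain tumour of glial cells. Its data are 1 small RNA library and 1 mRNA library of untreated U87MG cells. The small RNA library listed 1224 mature miRNAs with 11785001 reads and 10487 piRNA entries with 27299683 reads, 2.32 piRNA reads for each miRNA read. The mRNA library listed 21445 genes, with FPKM values that summed to 3532705. There was 1 library of each kind and no normal brain cell or other control, so the levels below are descriptions of this cell line. No value could be compared with a spread between replicates.

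A single miRNA, miR-21-5p, a widely studied oncogenic miRNA, made up most of the miRNA reads. It had 6933511 reads, or 58.8% of the total (95% interval 58.8 to 58.9%), 8.09 times the reads of let-7i-5p. let-7i-5p, of the tumour-suppressing let-7 family, followed with 857077 reads or 7.27% (7.26 to 7.29%), and miR-100-5p with 430317 reads or 3.65%. The next ranks held let-7a-5p (2.76%), miR-221-3p (2.35%), let-7f-5p (1.85%), miR-26a-5p (1.75%), let-7b-5p (1.43%), let-7g-5p (1.27%) and miR-27b-3p (1.07%). These 10 miRNAs held 82.2% of the miRNA reads (82.2 to 82.3%), and the first 15 held 85.9%. Ranks 11 to 15 were miR-7641 (0.823%), miR-222-3p (0.819%), miR-29a-3p (0.704%), miR-146a-5p (0.700%) and miR-92a-3p (0.664%). Of the 1224 listed miRNAs, 632 had at least 10 reads, and 221 had 1 read. The mature sequence listed for miR-21-5p was TAGCTTATCAGACTGATGTTGA and that for let-7i-5p was TGAGGTAGTAGTTTGTGCTGTT.

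**Figure D1:**
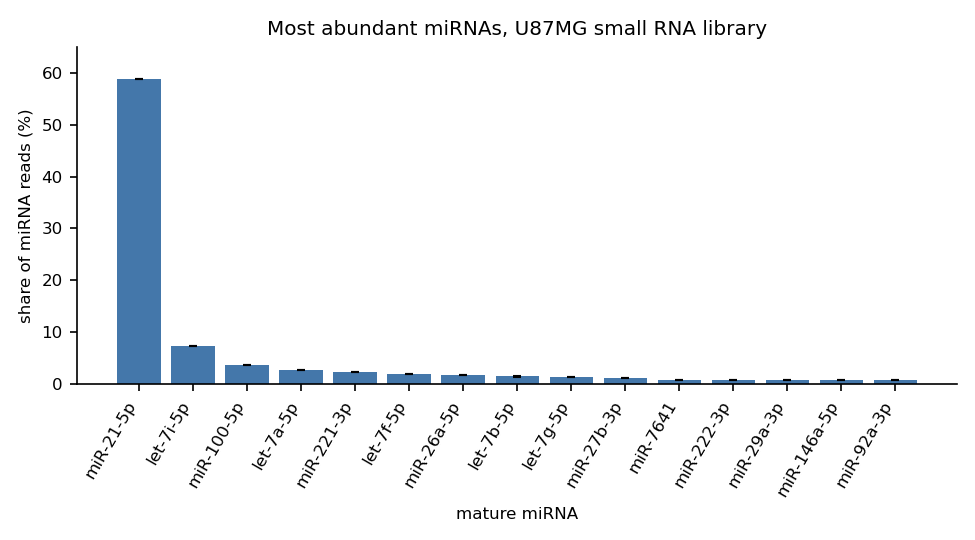
Share of miRNA reads in percent (vertical axis) for the 15 most abundant mature miRNAs (horizontal axis) of the U87MG small RNA library; error bars are exact 95% intervals of counting error and are narrower than the bars' outlines. miR-21-5p, at 58.8%, stands far above let-7i-5p at 7.27% and all other miRNAs.

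miRNAs that had been reported as raised in glioma were all present. All 24 members of that list had at least 10 reads, and together they held 66.2% of the miRNA reads (66.2 to 66.3%). Most of this was miR-21, with 58.9% over both arms; the other 23 members held 7.33% (7.31 to 7.34%), led by miR-221 (2.59%) and miR-26a (1.75%). Of 17 miRNAs reported as lowered in glioma, 13 had at least 10 reads, and the list held 1.27% (1.26 to 1.27%). Its highest members were miR-7 with 75769 reads, miR-181a with 24160 and miR-34a with 11316, while miR-124, the main miRNA of neurons, had no row. All 9 members of the let-7 family were detected, with 15.1% of the reads (15.1 to 15.2%); let-7i held 7.27%, let-7a 2.79% and let-7f 1.86%. The 17-92 family clusters, known to promote cell division, held 1.11% with 11 of 13 members detected, led by miR-92a, miR-25 with 24844 reads and miR-20a with 8483; miR-18b had no row.

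Brain-enriched miRNAs held a small share of the reads in the U87MG library, and those of other tissues held far smaller ones. Brain-enriched miRNAs held 0.428% of the reads (0.425 to 0.432%), mostly miR-9 with 31384 reads, ahead of miR-138 with 8720 and miR-128 with 7522; miR-124 and miR-488 had no row. Blood cell miRNAs held 0.0443%, nearly all of it miR-486 with 5173 reads, against 34 for miR-142 and 7 for the red cell miRNA miR-451a; miR-144 and miR-150 had no row. Epithelial miRNAs had 1191 reads, with miR-200b at 867, miR-200c at 209 and miR-200a at 102, and no row for miR-205. The liver miRNA miR-122 had 674 reads, and the endothelial miRNA miR-126 had 32. Muscle miRNAs had 90 reads, of which miR-1 had 71, miR-499a 17 and miR-206 2, and miR-133a, miR-133b, miR-208a and miR-208b had no row. Pluripotency miRNAs had 25 reads, of which miR-372 had 23 and miR-302a and miR-302b 1 each; miR-302c, miR-302d, miR-367, miR-371a and miR-373 had no row.

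A pair of large miRNA clusters differed strongly in level. The imprinted cluster at 14q32 had 49615 reads (0.421%, interval 0.417 to 0.425%), with 40 of 49 members at 10 reads or more, led by miR-381 with 14542, miR-127 with 12138 and miR-379 with 3365; miR-300 had no row. The primate cluster at 19q13, which is mainly placental, had 304 reads with 9 of 36 members at 10 reads or more. Its highest members were miR-516b with 56 reads, miR-512 with 51 and miR-520a with 41, and miR-518a, miR-519e, miR-520b, miR-520e, miR-520h, miR-521, miR-524, miR-525 and miR-527 had no row. The list of miRNA names regarded as fragments of other RNAs held 0.861%, of which miR-7641 had 97041 reads, miR-4485 1892 and miR-6087 1544. miR-7641 shared 18 of its 19 bases in a row with 5S rRNA. miR-4516, miR-1260a, miR-1274a, miR-1274b, miR-1280, miR-720, miR-1308 and miR-886 had no row. With miR-21-5p left out of list and total, the raised list held 17.99%, the lowered list 3.07% and the let-7 family 36.8% of the remaining reads.

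Most hairpins gave nearly all of their reads from 1 arm. Of 169 hairpins with both arms listed under the same name and at least 100 reads, the 5p arm was higher in 94 (55.6%, interval 47.8 to 63.2%) and the 3p arm in 75. Another 52 names with at least 100 reads had 1 arm only and were left out. They include let-7f, miR-26a and miR-92a, whose other arm is listed under numbered gene copies. In 114 hairpins 1 arm held at least 90% of the reads, and in 44 at least 99%. miR-21 had 99.9% of its reads on the 5p arm, 780 reads for each read of the 3p arm. miR-221 had 9.09% on the 5p arm and miR-27b 1.63%. In 29 hairpins the lower arm held at least 25%, such as miR-455 with 65.03% on the 5p arm (64.5 to 65.5%).

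The piRNA reads lay in very few database entries, and these carried the sequences of tRNA and rRNA. piR-60565 had 13089145 reads, or 47.9% of the piRNA reads (47.9 to 48.0%), and shared at least 20 bases in a row with tRNA-Glu-CTC. piR-35982 (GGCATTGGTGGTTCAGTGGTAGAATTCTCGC) had 5357269 reads or 19.6%, and matched tRNA-Gly-GCC. They were followed by piR-43771 (tRNA-Glu-CTC, 4.98%), piR-33151 (5S rRNA, 4.75%), piR-36378 (tRNA-Gln-CTG, 3.85%), piR-60576 (tRNA-Val-CAC, 2.58%), piR-36041 (tRNA-His-GTG, 2.44%), piR-35412 (tRNA-Lys-CTT, 1.60%), piR-35284 (tRNA-Gly-GCC, 1.01%) and piR-61648 (tRNA-Gly-GCC, 0.948%). These 10 entries held 89.7% of the reads (89.7 to 89.7%), and all 10 matched a tRNA or rRNA. Entries that match the same tRNA overlap in sequence, so their reads cannot be assigned separately with certainty. Of the 10487 entries, 1335 had at least 10 reads and 4124 (39.3%) had 1 read.

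Over all entries, 66 shared 20 bases with the tRNA, rRNA, Y RNA and 7SL RNA sequences, and these 66 held 96.4% of the piRNA reads (96.4 to 96.4%). tRNA matches held 89.4%, with tRNA-Glu-CTC at 53.4% and tRNA-Gly-GCC at 22.7%. rRNA matches held 5.999%, 7SL RNA 0.403%, Y RNA 0.365% and mitochondrial tRNA 0.214%. A first-base U is the usual mark of primary piRNAs. It was taken from the listed sequence of each entry, because the sequences of the reads are not given. Entries starting with U held 59.4% of the reads (59.4 to 59.5%) and made up 78.3% of the entries (77.5 to 79.1%). Without the 10 most abundant entries their share fell to 29.0% of the reads. Among the 10421 entries with no match, those starting with U held 41.4% of the reads (41.3 to 41.5%). Entries with an A at base 10, the mark of secondary piRNAs, held 5.88% of all reads. Among the entries with no match they held 28.5% of the reads and made up 32.8% of the entries.

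**Figure D2:**
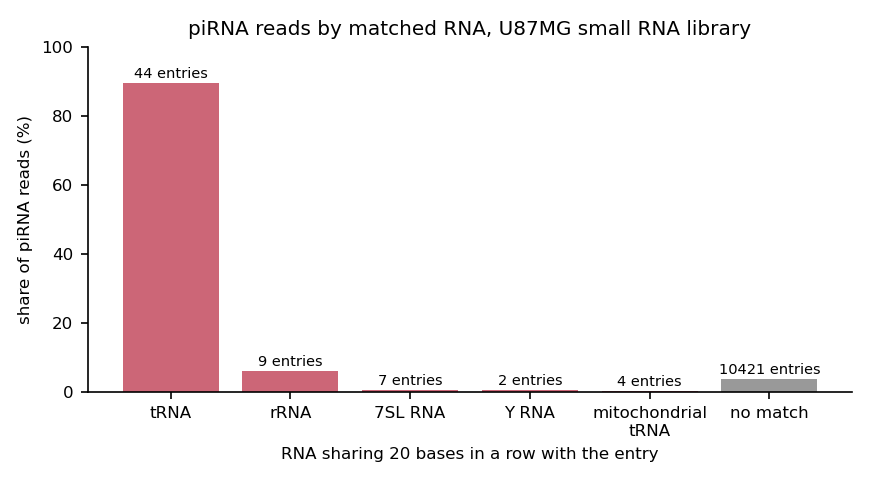
Share of piRNA reads in percent (vertical axis) by the RNA class that shares 20 bases in a row with the database entry (horizontal axis), U87MG small RNA library; the number above each bar is the number of entries. The 44 entries that match tRNA hold 89.4% of the reads, and the 10421 entries with no match hold 3.59%.

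In the mRNA library the highest FPKM values belonged to short structured RNAs. SNORD3A, the U3 small nucleolar RNA, was listed at 1436980 FPKM, 40.7% of the FPKM sum. RN7SL1 and RN7SL2, the RNA of the signal recognition particle, were listed at 445303 and 320422. RN7SK (175114), SNORD95 (167826), RMRP (140595), RPPH1 (71430), RN7SL3 (36239), SNORA63 (27130) and RNY1 (20392) completed the 10 highest, which held 80.4% of the FPKM sum. RNU2-2P (20056), a gene named Y_RNA (15689), RNY5 (15372), RNU4-2 (13099) and RNY3 (12203) completed the first 15, none of them protein-coding. Protein-coding genes held 10.6% of the sum. FPKM divides by length, so the values of RNAs shorter than a sequenced fragment depend on the unknown length rule of the program used.

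FTH1, the ferritin heavy chain, was the first coding gene, at rank 24 with 8036 FPKM, followed by GAPDH (3358), the calcium-binding S100A6 (2982), the actin-binding TMSB10 (2925), FTL (2825), B2M (2649) and VIM (2420). Of the 21445 genes 13859 were at 1 FPKM or more, and of 14376 coding genes 11139 were. Ribosomal protein genes made up 11.6% of the coding sum.

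Markers of mesenchymal glioblastoma were high, and few of the proneural type reached 1 FPKM. All 18 mesenchymal members were above 1 FPKM with a median of 191, above all 10000 random lists, led by VIM, LGALS1 (1976), TGFBI (1779) and ANXA1 (759); the lowest were RELB (10.3) and TRADD (8.65). Of 12 proneural members 2 reached 1 FPKM, SOX4 (2.18) and PDGFRA (1.96), with ERBB3 at 0.182, and 7, with OLIG2 and DLL3 among them, had no row. The proneural median over the 5 members with a row stood at percentile 9.20, or 3.41 among coding genes, both within the range of random lists. With genes lacking a row set to 0 the proneural median was 0, the lowest value possible, and stood at 2.22. The immune list, of the same size and also at a median of 0, stood at 2.505. The limit of 2.5 therefore does not separate these 2 lists. Of 11 classical members 9 were at 1 FPKM or more, AKT2 (53.1) and EGFR (29.4) well above PDGFA (3.95) and JAG1 (2.96). FGFR3 and SMO had no row. The classical median stood at percentile 42.2, but at 10.16 when only coding genes were drawn, both within the range of random lists. Neural stem markers stood at percentile 14.6, or 3.755 among coding genes, also within it. Of 12, 3 were at 1 FPKM or more: HES1 (6.24), NOTCH1 (4.75) and NES (1.38), followed by SOX9 (0.746), with no row for SOX2 and OLIG1.

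**Figure D3:**
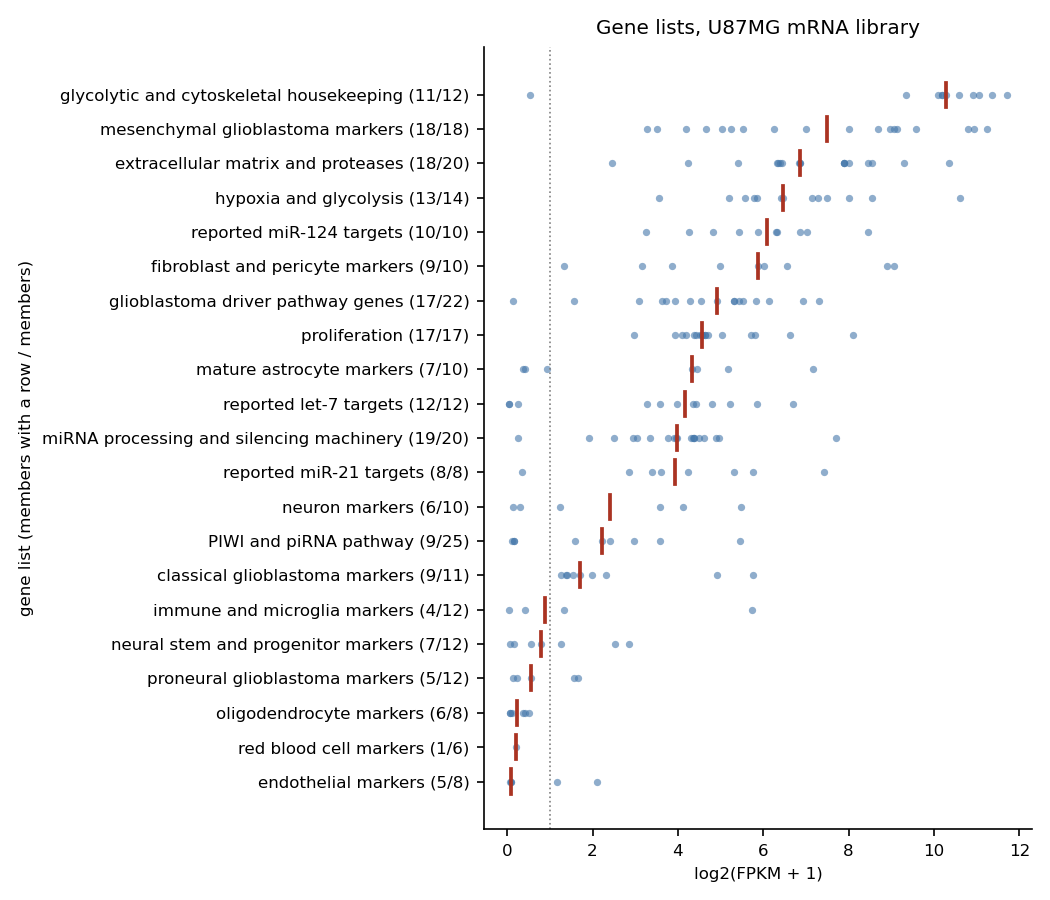
Expression as log2(FPKM + 1) (horizontal axis) of the members of the 21 gene lists (vertical axis, with members that have a row over all members) in the U87MG mRNA library; each dot is a gene, the red bar is the list's median over the members with a row, and the dotted line marks 1 FPKM. The housekeeping and mesenchymal lists lie highest, with medians of 10.27 and 7.50, and the endothelial list lies lowest at 0.10.

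Astrocyte markers were mixed. GJA1, a gap junction protein, was at 143 FPKM, GLUL at 35.3, ALDOC at 20.99 and SLC1A3 at 19.3, but GFAP, the filament protein of mature astrocytes, was at 0.331, and S100B and AQP4 had no row. The median of the members with a row stood at percentile 97.2, and with genes lacking a row set to 0 at 27.5; both lie within the range of random lists. Fibroblast and pericyte markers were high, with 9 of 10 at 1 FPKM or more and a median of 57.9, above all random lists. COL1A2 was at 535 and COL1A1 at 476, followed by FAP (92.7) and COL3A1 (64.2); RGS5 was at 1.52 and THY1 had no row. Extracellular matrix and protease genes had 18 of 20 members at 1 FPKM or more and a median of 115, above all random lists, with MMP2 at 1299.9, SPARC at 626, COL6A2 at 375 and ITGB1 at 348, and no row for MMP9 and COL4A1.

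Few markers of oligodendrocytes, endothelium, immune cells and red blood cells reached 1 FPKM. No oligodendrocyte marker of 8 reached 1 FPKM; MYRF (0.416), CNP (0.334) and MBP (0.285) were highest, and MOG and MOBP had no row. Endothelial markers had 2 of 8 at 1 FPKM or more, KDR (3.29) and TEK (1.23), with ESAM at 0.0718 and CDH5 at 0.0675 and no row for PECAM1 and CLDN5. These lists stood at percentiles 0.44 and 0.13, but at 11.8 and 10.98, within the range of random lists, once genes lacking a row were set to 0. Immune and microglia markers had 2 of 12, CD68 (52.3), a lysosomal protein, and CSF1R (1.51), with CD14 at 0.347 and ITGAM at 0.0342. PTPRC and AIF1 had no row. The list stood at percentile 16.3, or 5.31 among coding genes, both within the range of random lists. With missing rows at 0 its median was 0, the lowest value possible, at percentile 2.505, close to the limit of 2.5. AIF1 and MOG lie in the major histocompatibility complex, where 17 of 147 coding genes had a row. Their missing rows therefore do not bear on microglia or oligodendrocytes. Red blood cell markers had 0 of 6, with ALAS2 at 0.157 and no row for HBB and HBA1, at percentile 9.78. Neuron markers had 4 of 10, TUBB3 (43.5), SNAP25 (16.3), GAD1 (11.03) and MAP2 (1.37), with no row for ENO2 and STMN2. They stood at percentile 61.9, at 28.4 when only coding genes were drawn and at 15.3 with missing rows at 0, all within the range of random lists.

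Genes of cell division, hypoxia and the main glioblastoma pathways were expressed. All 17 proliferation genes were above 1 FPKM, with a median of 22.6 at percentile 99.9, led by CCND1 (272), PCNA (98.1), CCNB1 (55.0) and TOP2A (51.1) and ending with PLK1 (14.2) and CCNE1 (6.89). Of 14 hypoxia and glycolysis genes 13 were above 1 FPKM, with a median of 86.7 above all random lists, led by LDHA (1568), HIF1A (373), ADM (256) and BNIP3 (179), with ANGPTL4 (10.8) lowest and no row for PGK1. Of 22 driver pathway genes 16 were at 1 FPKM or more, with a median of 29.4 above all random lists. CDKN1A (157), CDK4 (121), MDM2 (69.2) and IDH2 (56.0) were highest. CDKN2A and CDKN2B, inhibitors of CDK4 and CDK6, had no row, nor did CDKN2C, TERT and MGMT. Housekeeping genes had 10 of 12 at 1 FPKM or more and a median of 1237, above all random lists, with GAPDH (3358), B2M (2649), EEF1A1 (2116) and ENO1 (1940) at the top. TPI1, a glycolytic enzyme, was at 0.458 and TUBB had no row.

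The genes that make and use miRNAs were expressed, and those of the piRNA pathway mostly were not listed. Of 20 miRNA machinery genes 18 were at 1 FPKM or more, led by RAN (206), DROSHA (30.1), XRN2 (28.5) and TNRC6A (23.4); DICER1 was at 19.3 and AGO2 at 12.6, while LIN28B was at 0.197 and LIN28A had no row. Their median of 14.9 stood at percentile 99.4, but at 93.7, within the range of random lists, when only coding genes were drawn. Of 25 PIWI pathway genes 6 were at 1 FPKM or more: SPOCD1 (42.6), MYBL1 (11.004), TDRD7 (6.90), TDRD3 (4.34), PLD6 (3.66) and TDRKH (2.001). Of the PIWI proteins themselves, PIWIL2 was at 0.109, PIWIL4 at 0.0775, and PIWIL1 and PIWIL3 had no row. The 9 members with a row had a median at percentile 56.9. With missing rows set to 0 the 25 members had a median of 0, the lowest value possible. It stood at percentile 1.13, below the range of random lists.

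Reported targets of the most abundant miRNAs were present in the mRNA library. All 8 miR-21 targets had a row and 7 were above 1 FPKM, with TPM1 (171) and SPRY2 (53.2) highest, TIMP3 at 17.98, and RECK (6.19) and BTG2 (0.278) lowest. Their median of 14.5 stood at percentile 95.8, and at 83.98 when only coding genes were drawn. Of 12 let-7 targets 9 were above 1 FPKM, led by HMGA1 (102), HMGA2 (56.5), NRAS (36.2) and MYC (26.9), with CCND2 (0.0369) and IGF2BP1 (0.0287) lowest. Their median of 16.998 stood at percentile 99, and at 93.8 when only coding genes were drawn. All 10 reported targets of miR-124, which itself had no row, were above 1 FPKM, with a median of 67.7 above all random lists, from ITGB1 (348), IQGAP1 (129), LAMC1 (115) and VAMP3 (78.6) down to RHOG (18.3) and AMOTL1 (8.57). Levels in 1 library do not show whether a miRNA lowers its targets.

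miRNAs and the genes listed as their hosts were compared across the 2 libraries. miR-21 had 6942400 reads and its host VMP1 was at 188 FPKM; miR-211 and its host TRPM1 both had no row. miR-10b had 59260 reads with its neighbour HOXD4 at 0.573, and miR-199a had 136 reads with its listed host DNM2 at 69.4. Strand was not checked for any pair, so a listed host need not carry the miRNA in its transcript. Across 50 pairs, with members lacking a row set to 0, Spearman's rho was 0.468 (permutation p = 0.00073) and Pearson's r was 0.513 (permutation p = 0.00011). miR-21 lay farthest from the median miRNA level, and miR-211, miR-208a and miR-483, all without reads, tied for the next place. Without miR-21 and miR-211 r was 0.420 (permutation p = 0.00317) and rho 0.400 (p = 0.00507), and without all 4 pairs r was 0.341 (permutation p = 0.0209) and rho 0.320 (p = 0.0300). Over the 45 pairs with both members above 0, r was 0.363 (permutation p = 0.0148) and rho 0.289 (p = 0.0554).

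Some missing rows in the mRNA library lay in stretches of neighbouring genes. Of 147 coding genes from GABBR1 to KIFC1, the major histocompatibility complex, 17 had a row (11.6%), against 69.0% of 20056 coding genes in all. HLA-B, HLA-C, TUBB and the cell type markers AIF1 and MOG were among those without. RPS9, a ribosomal protein gene, stood in a run of 25 coding genes without a row, RPS25 in a run of 8, ENO2 in a run of 7, PGK1 in a run of 4 and CDKN2A in a run of 24, interferon genes among them. These genes were picked because they had no row, and whether their runs are longer than chance would give was not tested. Of 156 genes that all cells use, 154 had a row, but how often other expressed genes lacked one was not tested. A missing row therefore does not by itself show that a single marker was not expressed. A low value may have the same limit. RPS18, in the complex, was at 1.81 FPKM against a median of 537 for 74 other ribosomal protein genes. TPI1 was at 0.458, with GAPDH at 3358.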

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

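Chosen only after the data were seen were the matches to tRNA and rRNA sequences with their variants, the setting of genes without a row to 0, and the host pairs without the farthest pairs, without hosts lacking a row or without miRNAs of several gene copies. Over all alternatives 131 values kept their side of the threshold or stayed within their interval or within 1.5 times of a count, 45 moved beyond that, 5 became weaker and 2 became stronger. Some of the 131 could not move. No listed gene was at 0, so drawing lists from genes above 0 repeated the main setting. Another pseudocount leaves rho as it is and can hardly change a list's percentile. The 131 therefore overstate how far the results held. No list went from one end of the random lists to the other, but with genes lacking a row at 0 the astrocyte list (27.5), the neuron list (15.3) and the PIWI pathway crossed their middle, as the neuron list (28.4) and the PIWI pathway (18.4) did among coding genes. The counts of detected RNAs depended on the minimum: 1224 and 326 miRNAs at 1 and 100 reads against 632, 10487, 2494 and 440 piRNA entries at 1, 5 and 100 reads against 1335, and 9225 genes at 5 FPKM against 13859. With 1 FPKM replaced by 0.1, the lists held 7 astrocyte, 6 neural stem, 4 proneural, 3 oligodendrocyte and 1 red blood cell genes; with 5 they held 1 neural stem, 0 proneural, 2 classical, 1 immune, 0 endothelial and 3 PIWI pathway genes. Leaving miR-21-5p out of list and total gave 17.99% for the raised list, 3.07% for the lowered list, 36.8% for let-7, 1.04% for brain, 2.70% for 17-92, 0.107% for blood, 0.00186% for muscle, 0.0139% for liver, 0.0245% for epithelial, 0.000660% for endothelial, 0.000515% for pluripotency, 1.02% for 14q32, 0.00627% for 19q13 and 2.09% for fragments. Leaving the fragment list out gave 83.0% for the 10 most abundant miRNAs, 66.8% for the raised, 1.28% for the lowered, 15.3% for the let-7 and 1.12% for the 17-92 list. The 10 most abundant piRNAs held 90.5% with contained sequences collapsed and 34.6% without entries matching tRNA or rRNA. Entries starting with U made up 78.3% of the piRNA entries. Their share of the reads was 29.0% without the 10 most abundant entries, 59.4% at lengths of 26 to 32 bases and 41.4% without matching entries. The share matching structured RNAs was 96.8% at 16 bases, 95.5% at 25 bases and 93.1% without the most abundant entry. Drawn from coding genes, the miRNA machinery stood at percentile 93.7 and the let-7 targets at 93.8. With genes lacking a row at 0, the oligodendrocyte list stood at 11.8 and the endothelial list at 10.98, both no longer apart. The PIWI pathway stood at 1.13, now apart, with a median of 0. The proneural list passed the limit at 2.22, but the immune list, of the same size and with the same median of 0, stood at 2.505. That step is therefore no real change. The host relation had a rho of 0.289 with both members above 0 and of 0.335 with hosts that have a row, and of 0.537 without miRNAs of several gene copies; the cause of the weaker value was not tested. Depth limited the least abundant lists, since 25 pluripotency reads gave an interval of 0.000137 to 0.000313%, and no depth was known for the FPKM values. No paired analysis was possible because each group holds 1 library. The planned comparison of piRNA entries with an annotated genome was not run.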

Other observations

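The lists of genes in the first 2 paragraphs, the test of all core genes, the share of piRNA reads matching structured RNAs and both tests of the major histocompatibility complex were chosen only after the result was seen. None of these lists was set against random lists. Of 14 cytokine and chemokine genes 11 had a row and all 11 were above 1 FPKM. CXCL8, a neutrophil attractant, was at 820 and IL1B at 420, well above CXCL2 (35.4), LIF (35.2) and IL6 (34.7), while CCL2 was at 8.45 and IL1A at 4.13. Metallothioneins, which bind metals, had 8 of 12 members above 1 FPKM, with MT2A at 1007, MT1X at 383 and MT1E at 180. HLA class II and its partners had 6 of 8 members above 1 FPKM, with HLA-DRB1 at 82.2 and CD74, the invariant chain, at 38.7, and no row for HLA-DPA1 and HLA-DPB1. In the class I list B2M was at 2649 and 7 of 10 members, HLA-B and HLA-C among them, had no row. The HLA genes lie in the major histocompatibility complex, where 11.6% of coding genes had a row. These values therefore do not show a difference between the classes. Long non-coding RNAs had 8 of 10 above 1 FPKM, led by GAS5 (6952), MALAT1 (3392) and SNHG1 (1020); the first and the last host small nucleolar RNAs, whose reads the values can include.

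Of the HOX genes with a row, 5 of 7 HOXD genes were above 1 FPKM, with HOXD8 at 8.83 and HOXD11 at 4.96. The same held for 1 of 9 HOXA genes (HOXA10, 1.12), 3 of 6 HOXB genes and 1 of 4 HOXC genes, and no difference between clusters was tested. The HOXD cluster contains miR-10b, which had 59260 reads, and the HOXB cluster contains miR-10a, which had 17013. In the 14q32 domain the non-coding MEG3 and MEG8 were at 6.89 and 6.91 FPKM, while the paternally expressed DLK1 and DIO3 had no row and RTL1 was at 0.232, beside 49615 miRNA reads of the cluster. All 13 proteins encoded in mitochondria had a row and were above 1 FPKM, with MT-CO1 at 1088. None of 13 cancer-testis antigens reached 1 FPKM, and the highest, MAGEA10, was at 0.283.

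Most piRNA reads lay in a few database entries, and the reads may be fragments of structured RNAs counted under piRNA names. Entries sharing 20 bases with tRNA, rRNA, Y RNA and 7SL RNA held 96.4% of the piRNA reads, as this explanation needs. If piRNAs of a PIWI pathway made up the remaining reads, entries starting with U were to hold at least their share of these reads. They were 78.6% of the entries without a match but held 41.4% of the reads. Without the 10 most abundant entries they held 47.4% (interval 47.3 to 47.6%, counting error only) against 78.6%. The read shares rest on the entry sequences, since read sequences are not given, and on the entries with most reads. Of the 1270 unmatched entries with 10 reads or more, 70.6% started with U. The read shares fell short of the prediction, and most of the remaining reads lay in entries without a first-base U. Entries with A at base 10 also had a smaller share of those reads (28.5%) than of the entries (32.8%). These shares do not decide how much of the remaining reads came from piRNAs. The share by entry describes the database, and the unmatched set was cleared with a partial set of sequences only. Of its 10 most abundant entries, 1 shared 15 bases in a row with a matched entry or a structured RNA, and 4 overlapped each other. Whether the tRNA fragments were made in the cell or by breakage during preparation was not tested.

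Genes that all cells use were missing from the FPKM list, which raises the question of what a missing row means. Of 156 ribosomal, proteasome, polymerase, chaperonin, initiation factor and coatomer genes 1.28% (exact 95% interval 0.156 to 4.55%) had no row (RPS9 and RPS25), which lies below the 5% set for a general loss of rows but does not show that every gene without a row was silent. Of core genes with a listed pseudogene copy 1 of 67 lacked a row, against 1 of 89 of the others (Fisher's exact test, two-sided, p = 1), and with 2 genes missing a loss through such copies stays open. Loss of reads where GRCh37 carries alternate haplotypes is a candidate explanation for the major histocompatibility complex, where 11.6% of coding genes had a row and none of 15621 other windows of 147 genes was as low, yet the MAPT region, which also has one, had rows for 69.2% of 13 coding genes, with 44.8% of other windows as low or lower, although 33.3% of its 9 genes with a row reached 1 FPKM, against a median of 80% in other windows, of which 3.52% were as low. Rows merely left out of the list would not lower the genes that remain, yet 41.2% of the 17 genes with a row in the complex reached 1 FPKM, less than in any other such window (median 79.1%), and RPS18 was at 1.81 against a median of 537 for 74 other ribosomal protein genes; a loss of reads by another route stays open.

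CDKN2A and CDKN2B had no row, miR-31 from the same region had 3 reads, and its host MIR31HG had no row; a loss of this region in the cell line may explain all of these. The run of coding genes without a row around CDKN2A, interferon genes left aside, held 8 genes from MLLT3 to DMRTA1 with MTAP, a widely expressed neighbour, among them, between SLC24A2 at 8.80 FPKM and ELAVL2 at 2.94. The planned test needed a value for MTAP, which has no row, so it could not decide. Of 2880 runs of unlisted genes, 97 were at least as long as these 8 genes, up to 65 genes. With its interferon genes the run held 24, so this count does not show how unusual the run is. A loss of the region and a gap in the FPKM list therefore cannot be told apart, although the miR-31 count comes from the other library.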
